A study of Drosophila melanogaster with 9 samples.

How the data were processed

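Libraries of 2 kinds from the intestine of Drosophila melanogaster were used. RNA-seq was made from sorted intestinal progenitors of controls (3 libraries) and of flies with RNA interference against swm (3 libraries). The controls were titled esgTS and the others swm. Each replicate came from 100 female flies with 30000 to 50000 GFP-positive cells. CLIP-seq was made from whole dissected intestines, as 2 immunoprecipitates taken with anti-Swm beads (Swm IP) and 1 library of the total lysate (input). All were depleted of ribosomal RNA, per the labels' protocols.

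The authors deposited raw read counts per gene for both kinds of library. The submitters' processing notes name cutadapt 2.9, STAR 2.7.3a, SAMtools 1.10, Subread 2.0.0, featureCounts and DESeq2, and the genome build, the annotation and the use of strand were not given in the sources used here. Per the file headers, each count table has 17807 rows and a gene length. That length leaves out introns in the RNA-seq table and equals the whole gene span in the CLIP-seq table, so intronic reads could enter the CLIP-seq counts. The authors' deposited tables of comparisons hold log2 fold changes and adjusted p-values from DESeq2, used only where they are named. A further 9 per-sample columns of those tables were not used. A single row without a gene name was left out of each count table; it held at most 5 counts in a library. Coordinates are from the BDGP6 annotation. Of the tested genes, 94.1% had their symbol there in both comparisons.

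Library totals ran from 14627251 to 19962224 counts in RNA-seq. They were 4615623 in the input, 2451369 in Swm IP replicate 1 and 8497190 in Swm IP replicate 2. Intervals from counts and floors cover counting error only. The labels do not say that replicates came from separate crosses, so p-values measure the spread between these samples, which could be technical in part.

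Counts were tested in R 4.3.3 with edgeR 4.0.16: filterByExpr (minimum count 10), TMM scaling, the robust quasi-likelihood fit and Benjamini-Hochberg adjustment, with a threshold of 0.05. Standard errors are the fold change divided by the root of the F statistic. CPM values use the TMM-scaled library sizes. The IP comparison has 1 residual degree of freedom, and the lone input was assumed to vary like the IP libraries. No mock immunoprecipitate was analysed here. A rule of size without a test took genes at least 2-fold higher in both IP libraries than in the input (log2 CPM, prior count 2). Gene lists with at least 5 tested members were compared with the other genes by camera in limma 3.58.1 at a preset correlation of 0.01, and again with an estimated correlation. The fry test, which asks whether a list's own genes move and makes no comparison with other genes, was run in its directional and mixed forms. Overlap of the comparisons was tested by the two-sided Fisher exact test over genes tested in both. For a gene at 0 in a group, the fold is a lower bound against 3 counts over the group; at 1 to 3 counts, the ratio has an exact 95% interval.

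The tests, the gene lists and the rule for named genes were fixed before the data were examined. The rule took swm; the 8 largest rises and 8 largest falls in RNA-seq and the 10 largest and 5 smallest IP ratios, among genes past the threshold with a mean of at least 5 CPM in a group, no overlap between groups and a name of their own; the 2 members of each list with the smallest adjusted p past the threshold, or else the 2 with the highest mean CPM (in the IP only for lists past the set test and for progenitor identity, Notch, cell cycle and adhesion); up to 8 genes past both tests in each direction; and esg, Dl, N, pros, nub, Myo31DF, shg and stg. Genes outside it are said to be chosen after their values were seen.

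On simulated counts with the real means and depths, the RNA-seq fit recovered 31 of 98 genes changed 2-fold and 68 of 102 changed 4-fold over 8899 genes, and 3.88% of its calls were false. The IP fit recovered 7 of 108 and 52 of 92 over 8375 genes, with 9.23% false calls. All simulated libraries, the input included, shared 1 spread set by mean expression, and genes were drawn independently. These shares are therefore not error rates of the real calls. Alternatives were other size factors, library sizes alone, DESeq2 1.42.0, no filter or a stricter one, a replicate block, each RNA-seq or IP replicate left out, the robust option off, a prior count of 0.5, other set tests and other definitions of the overlap. After the data were seen, a correction for gene length (loess offset, span 0.3), a fit without mitochondrial and tRNA genes, and strata of gene length were added.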

Results

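The study asked what the RNA-binding protein Swm does in the progenitors of the adult fly intestine. Gene expression was measured in progenitors with and without RNA interference against swm, and the RNA bound to Swm was measured in whole intestines. The sorted progenitors gave 3 control libraries of 19428033 to 19962224 counts and 3 libraries labelled swm RNAi of 14627251 to 19399264 counts. The whole intestines gave 2 Swm immunoprecipitates and 1 input.

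The swm transcript itself (2L, 19493251 to 19497978, BDGP6) did not differ between the groups. It stood at 159, 116 and 157 CPM in control replicates 1, 2 and 3 and at 159, 137 and 135 CPM in the libraries labelled swm RNAi. The log2 fold change was -0.0036 (SE 0.17, 95% interval -0.39 to 0.38, edgeR adjusted p = 0.998). Each direction below is therefore that of the libraries labelled swm RNAi. A difference in genetic background between the fly lines was not tested and cannot be told apart from RNA interference in these changes.

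Of 8899 genes tested, 208 were higher and 74 lower in the libraries labelled swm RNAi (edgeR quasi-likelihood, adjusted p below 0.05), and 1107 had an unadjusted p below 0.05. The 282 called genes became 141, 146 and 161 without swm RNAi replicates 1, 2 and 3. The 74 lower genes became 27, 24 and 26 without those replicates, and 116 without control replicate 1. Syt4, a synaptotagmin, had 0 counts in the controls and 29.7 ± 4.36 CPM (SD, n = 3) with swm RNAi, at least 607-fold higher. ftz, a segmentation gene of the embryo, had 0 counts in the controls and 18.4 ± 2.88 CPM (SD, n = 3), at least 373-fold higher. The serine protease homologs sphinx1 and sphinx2 went from 1 and 2 counts over the controls to 548 and 842, ratios of 690 (95% interval 123 to 27297) and 530 (146 to 4383). Ugt49B1, a UDP-glycosyltransferase, went from 1 count to 730, a ratio of 919 (164 to 36346). These families hold close copies, and the counting could have split reads between them. sphinx1 and sphinx2 lie side by side within the span of CG42458, on the opposite strand. CG42458 also rose, from 11 to 609 counts, so these rises may not be independent. Cyp6d2, a cytochrome P450, rose by a log2 fold change of 6.31 (SE 0.87), the transcription factor gene dysf by 5.82 (SE 0.59) and the neuropeptide receptor gene TrissinR by 5.85 (SE 1.20), with edgeR adjusted p = 0.0260, 0.00397 and 0.0289.

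Among genes with a name of their own, the largest falls were in fuss (log2 fold change -4.41, SE 0.82), pyd3 (-3.31, SE 0.45), the receptor tyrosine kinase gene Ret (-3.23, SE 0.42), Tektin-C (-3.18, SE 0.59) and ktub (-2.82, SE 0.44). ox, which encodes a subunit of respiratory complex III, fell by 2.12 on the log2 scale (SE 0.25), from 50.3 ± 8.75 to 11.6 ± 2.86 CPM (SD, n = 3 each). Prosap and the cytochrome P450 gene Cyp6a23 fell by 2.07 (SE 0.42) and 2.06 (SE 0.26). The edgeR adjusted p of these 8 genes ran from 0.000644 for ox to 0.0201 for Prosap.

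**Figure D1:**
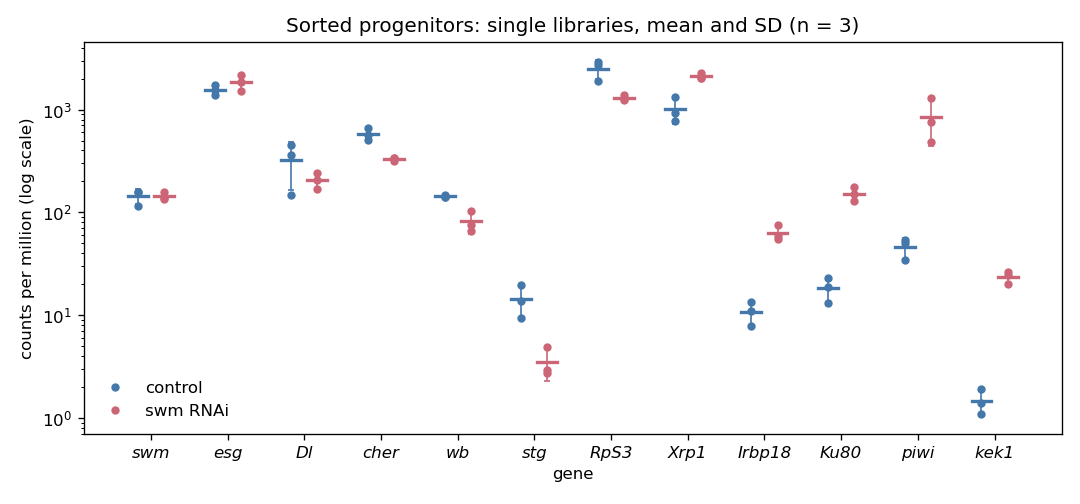
CPM (log axis) of 12 genes in the sorted progenitor libraries; points are single libraries, bars the mean and whiskers the SD (n = 3 per group). The swm points overlap between the groups, while RpS3 is lower and Irbp18, Ku80, piwi and kek1 are higher in every library labelled swm RNAi.

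Among genes of progenitor identity, 1 of 17 tested was called: cher, which encodes filamin, fell from 579 ± 79.8 to 332 ± 11.6 CPM (log2 fold change -0.80, SE 0.17, edgeR adjusted p = 0.0273). The progenitor gene esg had 1562 ± 164 CPM in control and 1852 ± 312 CPM with swm RNAi (SD, n = 3; log2 fold change 0.25, SE 0.18, adjusted p = 0.705). The Notch ligand gene Dl had a log2 fold change of -0.64 (SE 0.37), with 148 CPM in control replicate 2 against 456 and 360 CPM in the other controls, and its receptor gene N one of 0.12 (SE 0.20). None of the 20 Notch pathway genes passed over all genes, and 2 passed when adjusted over the list alone. The E-cadherin gene shg stood at -0.11 (SE 0.18), the enteroendocrine gene pros at -0.79 (SE 0.72) and the enterocyte genes nub and Myo31DF at 0.54 (SE 1.01) and -0.32 (SE 0.16), with no call. Of 27 adhesion and basement membrane genes, 1 was called, the laminin gene wb (-0.82, SE 0.18, adjusted p = 0.0372).

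Cell cycle and DNA replication genes were lower as a list (camera adjusted p = 0.00249, median log2 fold change -0.30, adjusted p = 0.884 with an estimated correlation). Single members went both ways. stg, the phosphatase that starts mitosis, fell by 2.03 (SE 0.43, edgeR adjusted p = 0.0258) and aurA, a mitotic kinase named after its value was seen, by 2.02. RnrL, a subunit of ribonucleotide reductase, rose by 1.40 (SE 0.20) and the origin recognition gene Orc1 by 1.28 (SE 0.24), and 46 of 50 members were not called. Adjusted over the list alone, 2 rose and 4 fell. Without control replicate 3 the list's camera adjusted p was 0.0915.

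Oxidative phosphorylation genes were lower as a list (camera adjusted p = 1.27e-06, median log2 fold change -0.35), with none of 29 members called singly. With an estimated correlation the adjusted p was 0.884. ATPsynC and ATPsynbeta had log2 fold changes of -0.42 (SE 0.16) and -0.36 (SE 0.16). Transcripts of the mitochondrial genome, at 5.27% of counts in control and 5.07% with swm RNAi, did not pass as a list: mt:CoI and mt:CoIII stood at 0.02 and 0.05.

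Digestive enzymes, the products of differentiated cells that a progenitor sort could carry along, were higher as a list (camera adjusted p = 0.0245, median 0.84; adjusted p = 0.884 with an estimated correlation), with none of 39 members called. They took 0.119% ± 0.0574 of counts in control and 0.240% ± 0.149 with swm RNAi (SD, n = 3), with the highest share, 0.410%, in swm RNAi replicate 3. Jon65Aiv and yip7 had log2 fold changes of 1.42 (SE 0.45) and 1.53 (SE 0.51). The camera adjusted p was 0.695 without control replicate 1, 0.0596 without control replicate 2 and 0.450 without swm RNAi replicate 3.

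Of 18 genes of JNK signalling and stress transcription, 2 rose over all genes, and 5 rose and 2 fell when adjusted over the list alone. The first 2 were Xrp1 and Irbp18, which encode bZIP partner proteins. Xrp1 went from 1010 ± 290 to 2111 ± 146 CPM (log2 fold change 1.06, SE 0.21, edgeR adjusted p = 0.0201) and Irbp18 rose by 2.55 (SE 0.25, adjusted p = 0.000164). Among 28 genes of EGFR, JAK-STAT and insulin signalling, kek1, an inhibitor of EGFR, rose by 4.02 (SE 0.36) and the growth factor gene Pvf2 by 1.85 (SE 0.19), dome, a receptor named after its value was seen, fell by 0.88 (SE 0.17), and 25 were not called. Of 83 ribosomal protein genes, only RpS3 was called, from 2498 ± 525 to 1297 ± 83.7 CPM (log2 fold change -0.95, SE 0.19, edgeR adjusted p = 0.0219).

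Among cell type markers, piwi, which guards the germline against transposons, went from 46.1 ± 10.6 to 849 ± 411 CPM (SD, n = 3 each), the 1 call among 11 ovary and germline genes. Syt4 was the 1 call among 16 enteroendocrine genes. None of 14 enterocyte, 12 visceral muscle, 6 neuronal or 6 fat body genes were called, with Tm1 at 0.04, elav at 0.91, pirk at 0.26, Msp300 at -0.26, Syx1A at 0.11, Yp2 at -0.18 and Yp3 at -0.16. Of 374 long noncoding RNAs, 6 rose and 1 fell. lncRNA:CR40469 went from 25.3 ± 10.2 to 2551 ± 269 CPM (log2 fold change 6.66, SE 0.33) and lncRNA:CR45517 rose by 1.67 (SE 0.17). The 1 that fell was lncRNA:CR46123, named after its value was seen. Of 211 small nucleolar and Cajal body RNAs, snoRNA:Psi18S-301 and snoRNA:Me18S-A1576 rose by 1.95 (SE 0.34) and 1.60 (SE 0.34).

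The other lists held no call over all genes, and 3 mRNA export and decay genes rose when adjusted over the list alone. Their 2 most abundant members were Rel (-0.29) and PGRP-LC (-0.11) in the Imd list, egr (0.18) and Diap1 (-0.05) in apoptosis, Hsc70-4 (-0.17) and Hsp70Bb (0.75) among chaperones, Mtor (-0.04) and sbr (0.18) in mRNA export and decay, arm (-0.24) and sd (0.02) in Wnt and Hippo signalling, Nop60B (0.04) and Myc (0.47) in ribosome biogenesis, Not1 (0.15) and pAbp (0.37) in the RNA granule list, E(spl)m3-HLH (0.25) in the Notch list, snRNA:7SK (0.38) and snRNA:U4:39B (0.40) among small nuclear RNAs, and tRNA:Val-CAC-2-5 (-2.17) and tRNA:His-GTG-2-1Psi (4.04) among tRNAs, as log2 fold changes. Control replicate 2 stood apart in several named genes, with Myc at 39.3 CPM against 778 and 337 CPM in control replicates 1 and 3, pAbp at 475 against 7286 and 4123 CPM, elav at 12.5 against 46.1 and 39.2 CPM and Msp300 at 1738 against 8446 and 5544 CPM. Of the 44 named genes called, 23 stayed called when each library in turn was left out. The 21 others, cher, wb, stg, RpS3 and Xrp1 among them, lost the call without at least 1 library.

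**Figure D2:**
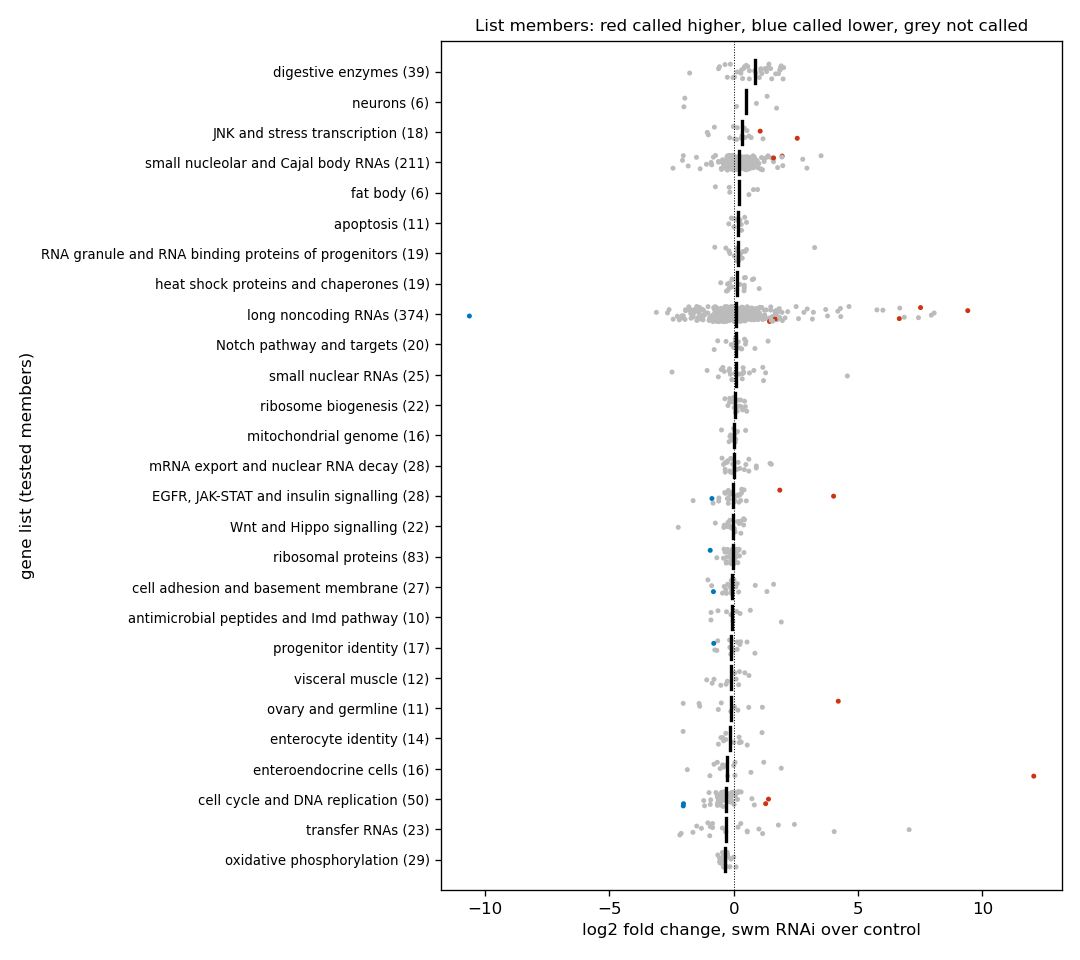
Log2 fold change of each tested member of each gene list, swm RNAi over control; red and blue points passed an adjusted p of 0.05 as higher or lower, grey did not, and the bar is the list's median. The medians of oxidative phosphorylation (-0.35) and cell cycle genes (-0.30) lie below 0 and that of digestive enzymes (0.84) above.

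The immunoprecipitates were compared with the input to ask which RNAs Swm binds. Of 8375 genes tested, 775 were higher and 751 lower in the IP (edgeR, adjusted p below 0.05); with library sizes alone, which moved the median of all genes from 0.0041 to 0.29 on the log2 scale, 1114 were higher and 417 lower. At least 2-fold higher in both IP libraries were 972 genes, and 863 were at least 2-fold lower in both. The 972 became 479 with the stricter filter, 1460 with library sizes alone and 1528 without Swm IP replicate 1. Leaving out a library drops a condition of the rule, so that last count could only rise. Of 30 lists tested, 19 passed camera with the preset correlation and none with an estimated correlation, where the smallest adjusted p was 0.534. With 1 residual degree of freedom the estimated setting decides little. Even the mitochondrial genome, with 34 of 37 members lower, had a camera adjusted p of 0.534 there. The ratio followed gene length: its median over genes was -1.18 in the shortest decile and 1.19 in the longest.

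Transcripts of the mitochondrial genome had the lowest list median: 34 of 37 were lower, with a median log2 ratio of -4.28, and their share of counts was 9.15% in the input and 0.693% and 1.34% in Swm IP replicates 1 and 2. mt:tRNA:Ala-TGC fell from 322 CPM in the input to 1.54 CPM in IP replicate 1 (log2 ratio -8.61, SE 0.40), and mt:tRNA:Leu-TAG and mt:tRNA:Arg-TCG had ratios of -7.81 (SE 0.45) and -7.58 (SE 0.37). mt:tRNA:Phe-GAA and mt:tRNA:Met-CAT had 0 counts in the IP libraries, at least 67.6-fold and 31.9-fold lower. Of 49 tRNAs tested, mitochondrial ones included, 26 were lower. The mitochondrial tRNAs belong to both lists, so these counts are not separate results, and nuclear tRNAs were not tested apart. Of 81 ribosomal protein genes, 72 were lower and none higher, with a median of -1.26; RpL38 stood at -3.51 (SE 0.25) and RpL39 at -2.62 (SE 0.25). Of 41 digestive enzymes, 33 were lower, Jon99Ci by 1.73 (SE 0.25) and Jon25Bi by 1.81 (SE 0.27). Of 29 oxidative phosphorylation genes 17 were lower, among them COX5B (-1.54, SE 0.24) and COX8 (-1.74, SE 0.28), and 5 of 8 small nuclear RNAs, among them snRNA:U6atac (-2.96, SE 0.33) and snRNA:U5:63BC (-2.12, SE 0.27). The heat shock genes Hsp70Ab (-1.68) and Hsp70Bb (-1.53), the peptidoglycan-degrading amidases PGRP-SC1a (-1.85) and PGRP-SC1b (-1.54), and the nucleolar genes Nop56 (-1.23) and Ns1 (-1.62) were also lower.

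The swm transcript had 124 CPM in the input and 206 and 180 CPM in the IP libraries (log2 ratio 0.64, SE 0.27, edgeR adjusted p = 0.0841). The genes with the largest ratios were rare in the input. Oamb, an octopamine receptor gene, had 0 input counts and 33.4 and 7.69 CPM in the IP libraries, at least 18.1-fold higher. ninaE, the main opsin gene, was at least 9.21-fold higher, Cngl 8.86-fold, Vm26Aa, an eggshell gene, 7.25-fold, dpr15 6.22-fold, dpr13 6.10-fold, ss 5.87-fold, Cpr50Ca 5.76-fold and Or83c 5.41-fold, all against 0 input counts. These bounds pool both IP libraries, which differed: Or83c had 13.1 and 1.43 CPM in replicates 1 and 2. With the length trend removed dpr15, dpr13, ss and Cpr50Ca lost the call, while Oamb, ninaE, Cngl, Vm26Aa and Or83c kept it. spok went from 2 input counts to 205, a ratio of 35.4 (95% interval 9.67 to 294).

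Part of the signalling and adhesion genes were higher. The Wnt and Hippo, RNA granule, adhesion, JNK and progenitor lists passed camera as higher, with adjusted p of at least 0.534 with an estimated correlation, and all but the RNA granule list turned to lower with the length trend removed, where none of the 5 passed. Of 23 Wnt and Hippo genes 8 were higher and none lower, among them the Hippo pathway genes kibra (1.31, SE 0.28) and wts (1.32, SE 0.29). Of 19 genes of the RNA granule list, 6 were higher, among them pum (155 CPM in the input, 325 and 340 CPM in the IP libraries) and Not1 (1.30, SE 0.33). Of 30 adhesion genes 7 were higher, among them the collagen gene vkg (3.58, SE 0.94) and the talin gene rhea (1.09, SE 0.28). In the JNK and stress list 6 were higher, with hep at 1.44 (SE 0.27) and Ets21C at 1.98 (SE 0.39), and 2 lower. Of 15 progenitor genes, hdc (1.29, SE 0.27) and cher (1.08, SE 0.28) were higher, and of 17 Notch genes 4, with mam at 1.45 (SE 0.30) and kuz at 1.01 (SE 0.28), although the Notch list did not pass (camera adjusted p = 0.0932). E2f1 was the 1 call among 45 cell cycle genes (1.38, SE 0.27, list camera adjusted p = 0.351). With the length trend removed, E2f1 (0.11), kibra (0.21), wts (0.43), mam (0.02) and Not1 (0.56) lost the call. rhea (-0.057), pum (-0.59), hdc (-0.25), cher (-0.12) and kuz (-0.49) lost it too and turned in sign, with none called lower. vkg (2.73), hep (0.78) and Ets21C (1.51) stayed called. The ratios of esg (0.18, SE 0.42), Dl (0.53, SE 0.46), N (0.74, SE 0.39), pros (0.37, SE 0.52), nub (0.66, SE 0.26), Myo31DF (0.12, SE 0.27), shg (0.28, SE 0.26) and stg (0.60, SE 1.45) did not pass.

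Some markers of other tissues were higher. Of 10 neuronal genes 3 were higher, with Sh at 3.33 (SE 0.60) and para rising from 3 input counts to 152, a ratio of 17.5 (95% interval 5.87 to 85.8). Of 10 Malpighian tubule genes 3 were higher, with NKCC at 1.37 (SE 0.37) and Irk3 at a ratio of 17.8 (4.80 to 149), and of 5 ovary and germline genes 3, with AGO3 at 1.26 (SE 0.34; -0.38 with the length trend removed). Yp2 was the 1 call of 8 fat body genes (1.26, SE 0.40). With genes at 0 put at their bound, the list medians were 1.66, 1.48, 2.27 and 1.18. Of 121 long noncoding RNAs 12 were higher, against 775 of 8375 over all genes. The 12 included lncRNA:CR44999 (2.91, SE 0.52) and lncRNA:CR43334 (1.46, SE 0.32). With the length trend removed these stood at 1.21 and 0.62 and lost the call. lncRNA:CR44999 starts at the same base and strand as Myc and spans it.

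Lists that did not pass camera also held calls, named here after their values were seen. Higher were sty, vn and Socs36E of 26 EGFR, JAK-STAT and insulin genes, trh and btl of 8 tracheal genes, Pxn of 5 hemocyte genes, Msp300 of 17 visceral muscle genes, Alp4 of 14 enterocyte genes and Ptx1 of 21 enteroendocrine genes. Lower were Npc2f, Alp9 and Ance among the enterocyte genes and AstC among the enteroendocrine genes. Of 11 small nucleolar RNAs 3 were higher, among them snoRNA:Psi28S-3342, and 3 lower, among them snoRNA:Me18S-A1806 and snoRNA:U3:9B. None of 12 apoptosis or 27 mRNA export and decay genes were called. When the trend with gene length was removed, a step chosen after the trend was seen, 140 genes were higher and 559 lower. With it removed, cher, hdc, rhea, pum and wb no longer stood above the input. The mitochondrial genome (median -2.69), ribosomal proteins (-0.60), digestive enzymes (-0.60) and tRNAs (-1.11, mitochondrial ones included) stayed lower. Long noncoding RNAs (adjusted p = 7.57e-05), fat body (0.000560) and ovary and germline genes (0.0455) stayed higher as lists, small nucleolar RNAs (2.61e-07) passed as higher and enteroendocrine genes (0.0133) as lower. These calls rest on the preset correlation. With an estimated correlation, before the trend was removed, the camera adjusted p was at least 0.534. It was 0.795 for small nucleolar RNAs and 0.717 for enteroendocrine genes. With the preset correlation these 2 lists had camera adjusted p of 0.309 and 0.590 before the correction. The small nucleolar call appeared only with the correction, which moved the list's median from 1.56 to 3.99. It also moved the short mt:tRNA:Ala-TGC from -8.61 to -5.81. The calls of oxidative phosphorylation (adjusted p = 0.0608), small nuclear RNAs (0.298), heat shock (0.0608), Imd (0.646), ribosome biogenesis (0.188), RNA granule (0.593), neuronal (0.0502) and Malpighian tubule genes (0.0608) were lost, and snRNA:U5:63BC turned to 0.26. The medians of Malpighian tubule genes (1.88 before, 2.00 after) and heat shock genes (-0.35 before, -0.27 after) moved little, so those losses do not show a part for length.

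**Figure D3:**
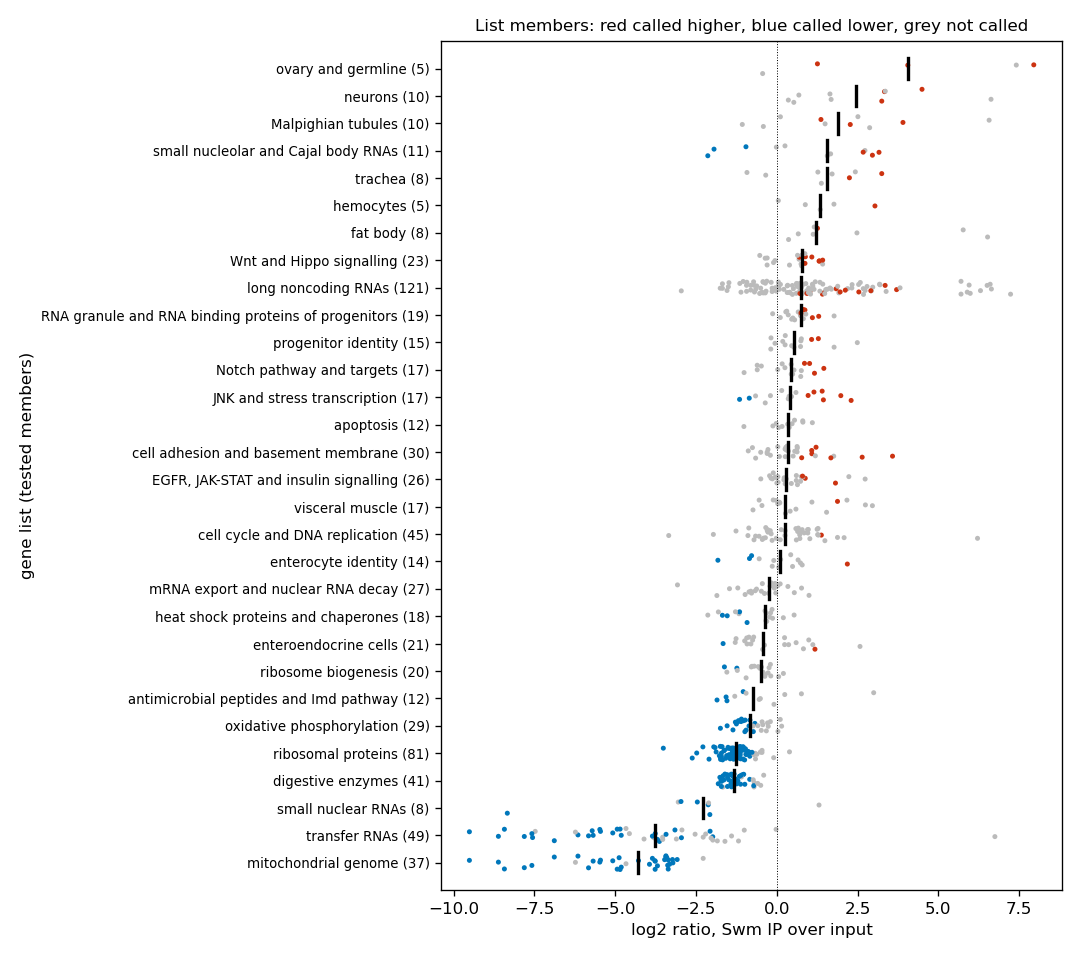
Log2 ratio of Swm IP over input for each tested member of each gene list, coloured as called higher (red), lower (blue) or neither (grey), with the median as a bar. The mitochondrial genome (median -4.28) lies lowest; every point above 6 is a gene with 0 counts in the input, whose fitted value is no bound.

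**Figure D4:**
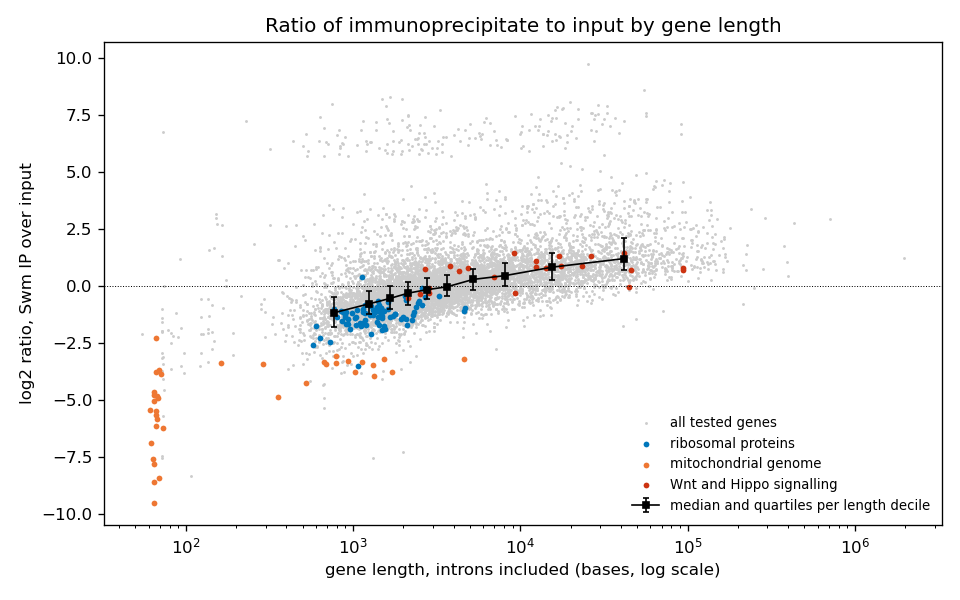
Log2 ratio of Swm IP over input against gene length with introns (log axis), all tested genes in grey, 3 lists in colour, squares and whiskers the median and quartiles of each length decile. The median rises from -1.18 to 1.19 over the deciles, and mitochondrial genes lie below the trend.

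The last comparison asked whether RNAs higher in the IP were those that changed in progenitors. Over 6993 genes tested in both, 12 of the 70 genes lower in the libraries labelled swm RNAi were higher in the IP, against 6.37 by chance (odds ratio 2.09, 95% interval 1.02 to 3.96, two-sided Fisher exact p = 0.0326). Of the 172 genes higher with swm RNAi, 10 were higher in the IP, against 15.6 by chance (odds ratio 0.611, 0.286 to 1.16, exact p = 0.141). This second odds ratio was 0.365 (exact p = 0.0343) with the authors' IP calls and 0.456 (exact p = 0.0526) by the rule of size. It was 0.736 (exact p = 0.452) within deciles of expression and 0.694 (exact p = 0.408) within deciles of gene length. The first odds ratio was 1.08 (exact p = 0.856) within deciles of gene length, a split chosen after the data were seen, 1.82 (exact p = 0.103) within deciles of expression and 0.570 (exact p = 0.485) by the rule of size. The 8 genes lower with swm RNAi that had the highest IP ratios were Dab (2.21), CG17716 (1.66), Gdh (1.60), wb (1.08), cher (1.08), Prosap (1.03), dve (1.00) and IP3K2 (0.93). With the length trend removed, wb, cher, Prosap, dve and IP3K2 stood at -0.35, -0.12, -0.46, -0.29 and -0.15 and CG17716 at 0.04, while Dab (1.48) and Gdh (1.20) stayed called. Among genes higher with swm RNAi they were side (4.25), Sema2b (2.27), CG42458 (1.72), 28SrRNA-Psi:CR40596 (1.24), cv-2 (1.21), obe (0.95), lncRNA:CR43459 (0.93) and CG1582 (0.93). With the length trend removed, side (2.81) and 28SrRNA-Psi:CR40596 (0.94) stayed called. Sema2b (0.97), CG42458 (0.58), cv-2 (0.15), obe (0.55), lncRNA:CR43459 (0.49) and CG1582 (0.77) lost the call. 28SrRNA-Psi:CR40596 is a pseudogene in the rDNA, and all libraries were depleted of ribosomal RNA. It has no value in the authors' deposited IP comparison. Dab, CG17716, Gdh, dve and IP3K2 had RNA-seq log2 fold changes of -1.12, -4.08, -1.19, -1.04 and -0.88. Those of Sema2b, CG42458, 28SrRNA-Psi:CR40596, obe, lncRNA:CR43459 and CG1582 were 1.24, 6.04, 1.95, 2.17, 0.90 and 1.48, cv-2 went from 52.1 to 112 CPM, and side went from 3 control counts to 237, a ratio of 99.4 (95% interval 33.6 to 486).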

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

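The length correction, the fit without mitochondrial and tRNA genes and the strata of gene length were chosen after seeing the data; the cause of the changes below was not tested. In RNA-seq, DESeq2 called 475 genes (320 higher, 155 lower), with 282 of the 282 calls shared, and no filter called 527 (351 higher, 176 lower). Leaving out each library gave 141 to 392 changed genes, 114 to 276 higher and 24 to 116 lower. The fewest calls, 141, 146 and 161, came without swm RNAi replicates 1, 2 and 3, and the most without control replicate 1. The authors' deposited table called 456 genes, 280 of them among the 282. The swm log2 fold change stayed between -0.15 and 0.06 across the settings, apart from the robust option off, where it was not taken. The same-numbered libraries did not deviate together (correlations -0.063, -0.049 and 0.0040), and the replicate block called 287 genes, 243 of them shared. With camera at an estimated correlation 0 lists passed in both comparisons. Directional fry, which tests a list's own genes for a move one way, passed 0 in both. Its mixed form, for change in either direction, passed 11 of 27 in RNA-seq and 0 of 30 in the IP. In the IP, with 1 residual degree of freedom, these failures decide little. The mitochondrial genome, 34 of 37 lower, had adjusted p of 0.534 by camera with an estimated correlation, 0.135 by directional fry and 0.130 by mixed fry.

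No paired analysis was possible for the IP because only 1 number is shared with the input. Genes higher in the IP were 512 by DESeq2 and 515 with the stricter filter, and 140 with the length trend removed; genes lower were 407, 498 and 559, and 417 with library sizes alone. The authors' deposited table called 879, 869 of them shared. The rule of size gave 1460 genes with library sizes alone and 479 with the stricter filter. It gave 1445 to 1528 with 1 IP library left out, which drops a condition and could only raise the count. With the length trend removed 9 lists passed. Turned in sign by it were rhea (-0.057), kuz (-0.49), AGO3 (-0.38), hdc (-0.25), cher (-0.12), pum (-0.59), snRNA:U5:63BC (0.26), wb (-0.35), Prosap (-0.46), dve (-0.29), IP3K2 (-0.15) and Myo31DF (-0.70), the genes Dl (-0.51), N (-0.49), pros (-1.11), nub (-0.61) and shg (-0.15), not called with or without it, and the lists of adhesion (adjusted p = 0.0824), JNK and stress (0.864), progenitor identity (0.0608) and Wnt and Hippo (0.982).

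The odds ratio of IP-higher among genes lower with swm RNAi was 0.570 by the rule of size, 1.47 with the authors' IP calls, 1.82 within expression deciles, 1.08 within length deciles, 1.60 with library sizes alone and 2.01 with the length trend removed, none past the threshold. Among genes higher with swm RNAi it was 0.365 with the authors' IP calls (exact p = 0.0343). Of the 65 named genes called in the IP, 20 lost the call with DESeq2; with the length trend removed 29 kept it, 25 lost it and 11 turned in sign. Input depth (4615623 counts) limits genes rare in the input.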

Other observations

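The tests on swm, the germline comparison, the partial rho with exon length and the choice of the DNA repair and glutathione S-transferase families were made after the results were seen; the other tests were set down first. Of 50 DNA repair genes tested, 15 were higher in the libraries labelled swm RNAi and none lower, against 2.18% higher among the other genes. They included both subunits of Ku, Ku80 (log2 fold change 3.05, SE 0.23) and Irbp (2.11, SE 0.29), the ligase gene DNAlig4 (2.06, SE 0.25), mre11 (1.04, SE 0.21), rad50 (1.19, SE 0.18) and nbs (1.45, SE 0.17), and RpA-70 (1.91, SE 0.18), RPA2 (0.94, SE 0.20) and RPA3 (2.03, SE 0.31). Of 27 glutathione S-transferase genes 6 were higher, among them GstE6 (4.41, SE 0.49) and GstE1 (2.09, SE 0.24), a family of close copies whose reads the counting could split. Both families were drawn up from genes already seen to be called, so their counts are not independent evidence.

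With all libraries thinned to the smallest total, the odds ratio of DNA repair genes was 18.8 with a 95% interval from 9.36, but thinning moved few calls (282 to 279) and the family was chosen from called genes, so a part of depth stayed open. RNA of ovary or germline cells stayed open too. The median of 11 such genes was -0.12 against 0.48, but the interval of the difference began at -0.127. A hypothesis is that lower RpS3 and higher Xrp1 and Irbp18 belong to one response that raised the repair genes. The design has no arm that changes RpS3 or Xrp1 alone, and a difference in genetic background between the fly lines was not tested.

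An exchange of single libraries between the groups was argued against as the reason that swm did not fall: each such exchange is one of the 9 other splits of the 6 libraries, and the highest of them called 0 genes. By correlation 0 of 6 libraries were closer to the other group, but control replicate 2 by a narrow margin (0.9321 against 0.9316), which decides little. Too few reads were argued against as well, since the interval of the fold change began at -0.39, above a 2-fold fall. Reads from the RNA interference construct counted as swm and a wrong label without a partner stay open, since counts per gene hold no positions. A fall limited to protein was not tested.

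The rise of the IP ratio with gene length (Spearman rho 0.610 across genes, which are not independent replicates) was not limited to genes with few input counts, since rho was 0.759 over 2713 genes with an input CPM of at least 50. Over 822 genes without introns rho was 0.410 (95% interval 0.345 to 0.480), as a bias by length itself would give. No RNA class was left out of these genes, and the short mitochondrial RNAs and tRNAs were lower as lists. That rho therefore cannot tell length from RNA class. Given exon length, the partial rho with intron length was 0.199 (0.174 to 0.223), as a larger part of unspliced RNA in the IP libraries would give, and that with exon length given intron length was larger, 0.422 (0.402 to 0.444). Both explanations stayed open, and either may act with the other. Without a mock immunoprecipitate here, no biological explanation was tested.

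With 6 libraries there are 10 splits, too few for a share under 0.05. The real split called 282 genes, the highest other split 0, and 1 split reached 282.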
